A study of Mus musculus with 11 samples.

How the data were processed

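RNA was measured by bulk RNA sequencing in 11 samples of acute myeloid leukaemia (AML) from mice that carried Flt3-ITD, an activating internal tandem duplication of the cytokine receptor gene Flt3, together with NHD13, a NUP98-HOXD13 fusion transgene. Per the labels, 6 samples were heterozygous for Ifnar1 (Ifnar1 +/-) and 5 lacked both functional copies (Ifnar1 -/-). Ifnar1 encodes a subunit of the receptor for type I interferons. Per the labels' protocols, RNA was extracted with a Qiagen micro-scale column kit and libraries were made with a Clontech SMART-type kit. The submitters' processing notes name bcl2fastq and DRAGEN, with no version. The genome build and the annotation behind the counts are not given in the sources used here.

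The deposited values are estimated counts of reads per gene, with up to 2 decimals. Per the submitters' processing notes the tools above were used, but their roles are not given. They were not scaled between samples, as the column totals of 25583642 to 38728143 show. Between 10.0% and 11.3% of a library's values were not whole. The table held 55774 rows. In it, 168 Ensembl identifiers occurred more than once, in 455 rows that were identical copies, and 287 copies were dropped to leave 55487 genes. Gene symbols were taken by Ensembl identifier from a reference table, which matched 55141 identifiers. Rows without a symbol held at most 0.0219% of a library's counts and stayed in the library totals. Gene positions came from GENCODE release M21 on GRCm38.

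Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by genotype, which left 14521, and libraries were scaled with TMM factors. Genotype was tested with the quasi-likelihood F-test (glmQLFit with robust=TRUE, glmQLFTest), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are Ifnar1 -/- against Ifnar1 +/-, with SE taken as the absolute log2 fold change divided by the square root of F. Levels are TMM-scaled CPM (counts scaled to a common library total). With 11 libraries split into 6 and 5, an exact permutation test has 462 assignments and a smallest p of 0.00216. Such tests were two-sided. Nothing in the labels says that the samples of a genotype came from separate mice, so p-values measure the spread between these samples.

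A total of 28 gene lists was fixed before the data were examined, and so were the tests, the rule for named genes and most of the alternatives. The lists cover interferon-stimulated genes, genes inducible by interferon gamma, class I and class II antigen presentation, interferon receptors with JAK-STAT members, nucleic acid sensors, STAT5 and MAPK targets downstream of Flt3-ITD, the Hox programme, cell cycle, MYC and ribosome biogenesis, oxidative phosphorylation, NF-kB inflammation, p53 and apoptosis, immediate early genes, mitochondrial transcripts, genes near Ifnar1 and 12 cell types. For 7 list members the older symbol of the reference was used. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the 28 lists. Camera with an estimated correlation and fry were alternatives. A list score is the mean over tested members of log2 CPM (prior count of 2), centred per gene. Spread within a genotype is the mean pairwise distance (1 minus Spearman's correlation) over the 2000 most variable genes. For Ifnar1 the permutation test used log2(CPM + 1).

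Named genes are Ifnar1, the genes that passed (up to 12 per direction) or otherwise up to 6 per direction with the smallest unadjusted p, up to 4 members of a described list with the smallest p, and for cell types 2 members with the highest mean level. Predicted and clone-named genes were left out. Other genes in the description of single libraries were chosen after their values were seen. Xist and the Y-linked genes served only as a check of sex. Intervals of shares are 95% Wilson intervals, and these, like the limit of 3 counts given for genes with 0 counts, cover counting error only.

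Alternatives were DESeq2 1.42.0, limma voom with quality weights, DESeq2 size factors or upper-quartile factors in edgeR, no filter, a filter of 5 CPM in 5 samples, other thresholds, robust=FALSE, thinning to the shallowest library, leaving out each library, the replicate number as a block, and 1 surrogate variable from sva 3.50.0. A covariate for the B cell list score and a fit without a pair of libraries that stood apart were added after seeing the data. A sex covariate was planned only if both sexes occurred in both genotypes, which was not so.

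The edgeR and camera steps were tested on simulated data for this comparison, with 14521 genes of which 200 were changed. At a dispersion of 0.05, 89.6% of 2-fold, 98.5% of 4-fold and 100% of 8-fold changes were called, and 6 unchanged genes were called. With the dispersions estimated from these libraries, 4.48%, 28.4% and 54.5% were called, and 2 unchanged genes were called. A planted list of 48 genes lowered 1.5 times had an adjusted p of 0.00100 in the camera test at these dispersions. Of 27 random lists 0 were called. Genes were simulated independently of each other, so this does not show how often camera calls lists whose members vary together. The estimated correlation within the cell cycle list, for example, was 0.93. No pair of libraries of a genotype was a repeat, since the mean chi-square per gene was at least 68.7. Figures were drawn with matplotlib 3.10.9.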

Results

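The series measured gene expression in AML from mice with Flt3-ITD and the NHD13 transgene, and its title speaks of changes in cell identity and of a variable dependence on interferon. The comparison the labels give is Ifnar1 -/- against Ifnar1 +/-, that is, AML with and without loss of the type I interferon receptor subunit. There were 6 Ifnar1 +/- and 5 Ifnar1 -/- libraries. Library totals ran from 25583642 to 38728143 estimated counts, and 13293 to 14754 genes had at least 10 counts.

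Ifnar1 transcript did not separate the genotypes. Its level was 61.0 ± 16.9 CPM (SD, n = 6) in Ifnar1 +/- AML and 69.2 ± 38.4 CPM (SD, n = 5) in Ifnar1 -/- AML. The Ifnar1 +/- libraries 1 to 6 had 39.3, 50.03, 84.5, 68.5, 72.3 and 51.4 CPM, and the Ifnar1 -/- libraries 1 to 5 had 36.3, 54.2, 133, 47.3 and 74.8 CPM. The log2 fold change was 0.18 (SE 0.34, edgeR adjusted p = 0.9998), and the exact permutation p was 0.838. Ifnar1 (ENSMUSG00000022967) lies on the plus strand of chromosome 16, from 91485238 to 91507441 in GRCm38. A count over the whole gene does not show whether part of it is deleted, so the transcript level neither checks nor contradicts the labels, and genotype below means the labelled genotype. The sign of the fold change turned without Ifnar1 -/- library 3 (-0.20) and in limma voom (-0.25).

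Lineage transcripts varied widely among the AMLs of both genotypes. Early B-lineage genes were abundant in Ifnar1 +/- libraries 3, 4 and 5 and in Ifnar1 -/- libraries 3 and 5. In these 5 libraries the B-lineage transcription factor gene Ebf1 had 531 to 745 CPM, and the surrogate light chain genes Igll1 and Vpreb1 had 1057 to 2823 and 338 to 1268 CPM. Transcripts of Fcer2a, a marker of mature B cells, were at most 0.314 CPM in any library. Ifnar1 +/- libraries 1, 2 and 6 and Ifnar1 -/- libraries 1 and 4 had 41.0 to 112 CPM of Mecom, a stem-cell transcription factor gene. Gata1, which encodes an erythroid and megakaryocytic transcription factor, had 61.04, 150, 11.5, 9.97, 6.11 and 231 CPM in Ifnar1 +/- libraries 1 to 6 and 264, 199, 3.26, 165 and 60.99 CPM in Ifnar1 -/- libraries 1 to 5. Ifnar1 -/- library 2 had list scores of -0.50 for erythroid and -1.75 for megakaryocyte and platelet genes, so its Gata1 alone does not place it in these lineages.

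Single libraries stood apart by myeloid and erythroid transcripts. Ifnar1 -/- library 2 had 47695 CPM of the eosinophil granule gene Prg2 and 24050 CPM of the neutrophil granule gene Ngp, against at most 1166 and 2149 CPM in the other 10 libraries. Globin genes took 11.8% of the counts (95% Wilson interval 11.7% to 11.8%) in Ifnar1 +/- library 6 and 0.0956% to 1.42% in the others. Hoxd13, the homeobox gene of the NHD13 fusion, was counted in all 11 libraries at 3.52 to 8.68 CPM. Counts of the mouse gene do not show whether the fusion was expressed. Xist had 1157 to 2399 counts in 10 libraries and 3 in Ifnar1 -/- library 2, which had 817 counts of the Y-linked gene Ddx3y.

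**Figure D1:**
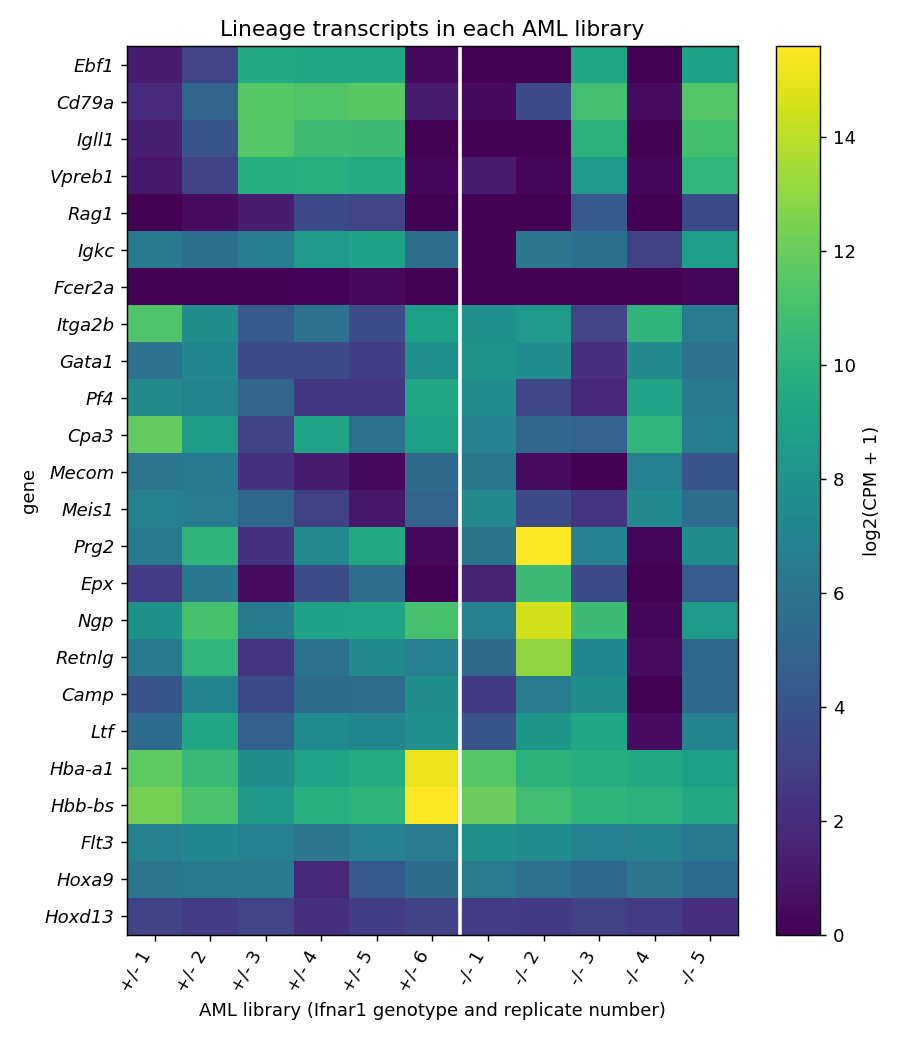
Levels of 24 genes (rows) in the 11 AML libraries (columns, Ifnar1 +/- to the left of the white line and Ifnar1 -/- to the right) as log2(CPM + 1). B-lineage genes such as Ebf1 are high in 5 libraries from both genotypes, and Prg2 and Ngp are highest in Ifnar1 -/- library 2.

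The spread among AMLs did not differ detectably between genotypes. The mean pairwise distance was 0.689 among Ifnar1 -/- and 0.628 among Ifnar1 +/- libraries (exact permutation p = 0.418). The difference of 0.0616 was 0.00147 without Ifnar1 -/- library 3. The first principal component held 55.3% of the variance of the most variable genes. On it the libraries ran from -96.5 in Ifnar1 -/- library 4 to 109 in Ifnar1 +/- library 5. No difference between genotypes was detected along it (exact permutation p = 0.699).

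No single gene passed edgeR's test between genotypes. The genes with the smallest p among those lower in Ifnar1 -/- AML were Prf1, Nrp2, Scamp5, Ifit1, Fyttd1 and Mgarp. None of them passed in edgeR, while DESeq2 called Prf1, Nrp2 and Fyttd1. Prf1, which encodes the pore-forming protein perforin, had 11.3 ± 13.4 CPM (SD, n = 6) in Ifnar1 +/- and 0.830 ± 0.676 CPM (SD, n = 5) in Ifnar1 -/- AML, a log2 fold change of -3.76 (SE 0.87). Ifnar1 +/- library 1 had 38.4 CPM of it, and without that library the log2 fold change was -2.83. Fyttd1, an mRNA export factor gene, had 54.3 ± 5.06 and 37.7 ± 4.06 CPM, with all 6 Ifnar1 +/- libraries above all 5 Ifnar1 -/- libraries and a log2 fold change of -0.53 (SE 0.14). Nrp2, the gene of a neuropilin co-receptor, had 2.04 ± 1.79 and 0.111 ± 0.124 CPM, and Scamp5 had 1.05 ± 0.362 and 0.212 ± 0.201 CPM. Mgarp was also low, at 1.39 ± 0.891 and 0.254 ± 0.179 CPM.

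Among genes with higher values in Ifnar1 -/- AML, the smallest p belonged to Nxnl2, Syne1, Dennd1c, Paox, Kif21b and Trpm2, none of which passed. Syne1, which encodes a nuclear envelope spectrin-repeat protein, had 84.5 ± 121 CPM in Ifnar1 -/- and 12.7 ± 7.61 CPM in Ifnar1 +/- AML. Dennd1c had 46.3 ± 25.8 and 20.3 ± 6.44 CPM, and Paox, a polyamine oxidase gene, had 11.5 ± 8.94 and 4.28 ± 1.58 CPM. Log2 fold changes of these 6 genes ran from 1.19 to 4.09. For Syne1, Kif21b, Trpm2 and Nxnl2 the highest value was in Ifnar1 -/- library 2, with 299.8, 93.7, 50.1 and 12.5 CPM. Without that library their log2 fold changes were 1.28, 0.90, 1.45 and 2.16, against 2.73, 1.89, 3.05 and 4.09 with it.

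Of 14521 genes, 0 had an adjusted p under 0.05 in edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 112 lower and 177 higher genes, 289 in all, where 726 would be expected by chance. DESeq2 called 3 genes on the same table, all lower in Ifnar1 -/- AML (Prf1 and Fyttd1 with adjusted p = 0.00600, Nrp2 with adjusted p = 0.0173), and limma voom called 0. All Ifnar1 +/- libraries lay above all Ifnar1 -/- libraries for 11 genes and below them for 7, 18 being fewer than the 62.9 that chance gives (0.433% of genes). The biological coefficient of variation was 0.782.

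Interferon-stimulated genes were lower in Ifnar1 -/- AML as a group in camera with a preset correlation (adjusted p = 1.1e-15), but did not pass with an estimated correlation (unadjusted p = 0.00272, adjusted p = 0.0762 over 28 lists) or in fry (adjusted p = 0.235). Of 49 tested members, 40 had lower and 9 had higher fitted values, with a median log2 fold change of -0.50. Ifit1, an antiviral RNA-binding protein gene, had 3.97 ± 3.12 CPM (SD, n = 6) in Ifnar1 +/- and 0.436 ± 0.298 CPM (SD, n = 5) in Ifnar1 -/- AML, a log2 fold change of -3.17 (SE 0.83). Rtp4 had 9.35 ± 8.81 and 1.06 ± 1.47 CPM (-3.13, SE 0.95). The oligoadenylate synthetase family members Oasl1 and Oas2 had 5.87 ± 5.67 against 0.479 ± 0.790 CPM (-3.59, SE 1.14) and 1.34 ± 1.01 against 0.187 ± 0.294 CPM (-2.79, SE 1.02). Without Ifnar1 -/- library 5 the log2 fold changes of Rtp4, Oasl1 and Oas2 were -4.50, -5.51 and -4.45.

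No member of the list passed, over all genes or adjusted over the list alone, and 8 had an unadjusted p under 0.05. The interferon-stimulated gene score was 0.45 ± 0.39 (SD, n = 6) in Ifnar1 +/- and -0.54 ± 0.57 (SD, n = 5) in Ifnar1 -/- AML, a difference of -0.998 (exact permutation p = 0.0152, adjusted p = 0.424 over the scores of the 28 lists). Scores of Ifnar1 -/- libraries 1 to 5 were -0.59, -1.11, -0.90, -0.49 and 0.37, and those of Ifnar1 +/- libraries 1 to 6 were -0.01, 0.89, 0.89, 0.53, 0.33 and 0.09. Reads of Ifit and Oas family members can be split between near-identical copies, so their single values are uncertain.

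**Figure D2:**
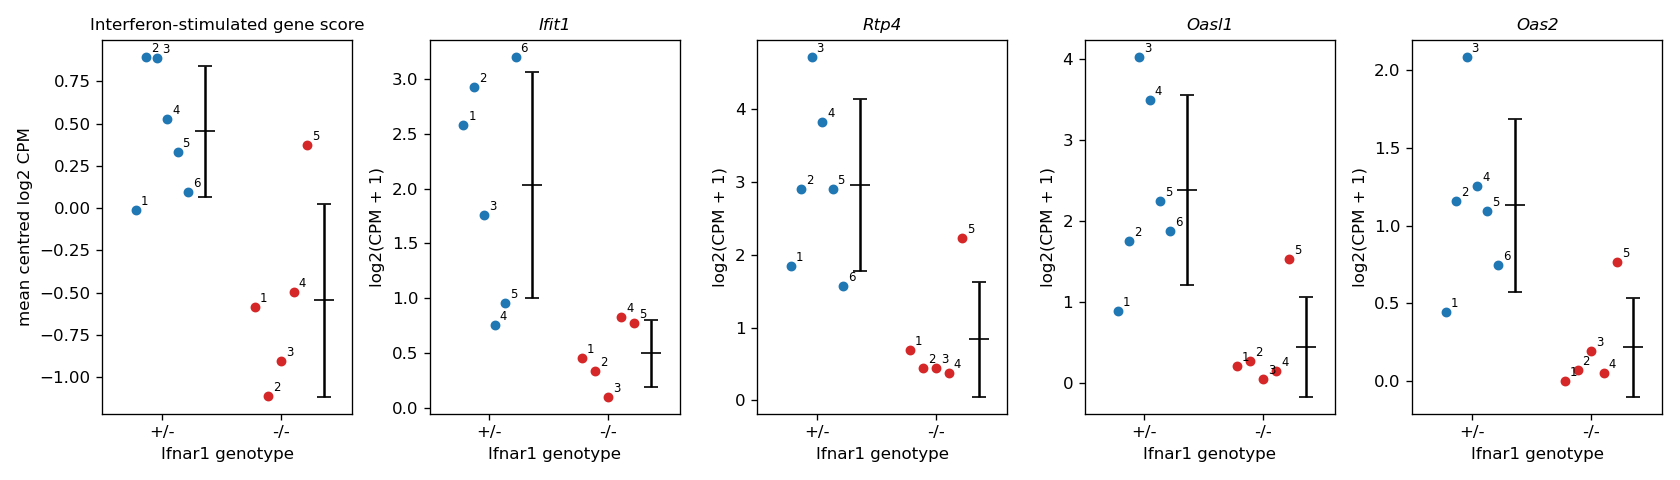
Interferon-stimulated gene score (left, mean centred log2 CPM) and levels of Ifit1, Rtp4, Oasl1 and Oas2 (log2(CPM + 1)) in 6 Ifnar1 +/- (blue) and 5 Ifnar1 -/- (red) libraries. Each point is a library with its replicate number, and bars give mean and SD. Ifnar1 -/- library 5, with a score of 0.37, lies within the range of the Ifnar1 +/- libraries.

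Genes inducible by interferon gamma were lower as a group with the preset correlation and did not pass with an estimated one. Of 19 tested members 15 had lower values, with a median log2 fold change of -0.39 (camera adjusted p = 0.0244, adjusted p = 0.843 with an estimated correlation). The immunity-related GTPase gene Irgm1 had 74.8 ± 11.02 CPM (SD, n = 6) in Ifnar1 +/- and 46.0 ± 17.2 CPM (SD, n = 5) in Ifnar1 -/- AML, and Iigp1 had 1.10 ± 1.42 and 0.118 ± 0.138 CPM. Irf1, the gene of an interferon regulatory factor, had 42.9 ± 9.92 and 53.9 ± 13.8 CPM. Upp1 had 7.003 ± 6.83 and 20.8 ± 30.8 CPM. Neither passed the test, and without Ifnar1 -/- library 2, which had 74.9 CPM of Upp1, its log2 fold change was 0.062 against 1.57 with it. Class I antigen presentation did not pass (13 of 20 lower, median -0.11, adjusted p = 0.0834). B2m, the invariant class I chain, had 1629 ± 1261 and 887 ± 258 CPM (log2 fold change -0.88, and -0.33 without Ifnar1 +/- library 1 with its 4182 CPM), Erap1 had 67.5 ± 10.2 and 50.9 ± 11.1 CPM, and Tap2 had 266 ± 98.3 and 383 ± 118 CPM.

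The lists of receptors and sensors upstream of the response did not pass the test. The list of interferon receptors and JAK-STAT members had 9 of 18 lower (adjusted p = 0.873), and nucleic acid sensors had 11 of 20 lower (adjusted p = 0.396). Class II antigen presentation had 3 of 10 lower (adjusted p = 0.786). The interferon genes Ifnb1 and Ifna4 had 0 counts in every library, which allows at most 0.0724 to 0.155 CPM per library.

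STAT5 and MAPK targets downstream of Flt3-ITD were lower in Ifnar1 -/- AML as a group with the preset correlation only. They did not pass in fry (adjusted p = 0.525), and their score did not differ detectably (exact permutation p = 0.180). Of 25 members 17 had lower values, with a median log2 fold change of -0.27 (camera adjusted p = 0.00461, adjusted p = 0.104 with an estimated correlation). Bcl2l1, which encodes the survival protein BCL-XL, had 362 ± 123 CPM (SD, n = 6) in Ifnar1 +/- and 198 ± 80.2 CPM (SD, n = 5) in Ifnar1 -/- AML. The signalling inhibitor genes Spred1 and Spry2 had 16.0 ± 3.87 against 8.39 ± 3.68 CPM and 21.7 ± 14.3 against 9.03 ± 7.03 CPM. The immediate early gene Egr1 had 45.1 ± 46.6 and 13.6 ± 8.18 CPM. None of these genes passed by itself.

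Growth lists were lower by small amounts with the preset correlation only. Their scores did not differ detectably between genotypes. The exact permutation p was 0.658 for cell cycle, 0.420 for MYC and ribosome biogenesis and 0.275 for mitochondrial transcripts. The cell cycle list had 28 of 30 members lower (median -0.34, camera adjusted p = 0.0166, adjusted p = 0.861 with an estimated correlation), among them the mitotic kinesin gene Kif11 with 67.9 ± 41.3 against 45.9 ± 28.8 CPM and the cyclin gene Ccnb1 with 226 ± 127 against 163 ± 125 CPM. MYC and ribosome biogenesis had 19 of 23 lower (median -0.23, adjusted p = 0.00461, adjusted p = 0.843 with an estimated correlation), with Eif4e, a translation initiation factor gene, at 226 ± 65.3 against 167 ± 44.1 CPM and Nolc1 at 200 ± 81.2 against 138 ± 54.8 CPM. Mitochondrial transcripts had 11 of 13 lower (median -0.13, adjusted p = 0.0451, adjusted p = 0.843 with an estimated correlation), with mt-Nd1 at 1306 ± 180.5 against 1011 ± 204 CPM. The cell cycle score was -2.01, -0.47, 0.93, 1.12, 1.16 and 0.12 in Ifnar1 +/- libraries 1 to 6 and -0.58, -0.59, 1.10, -1.75 and 0.97 in Ifnar1 -/- libraries 1 to 5. In the same order the B cell list score was -3.11, -0.99, 3.70, 4.65, 4.87 and -4.20, and -4.75, -4.05, 3.84, -4.70 and 4.74.

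In all, 11 of the 28 lists passed with the preset correlation and 0 with an estimated correlation or in fry, and the count was 5 without Ifnar1 +/- library 1, 6 without Ifnar1 +/- library 4 and 7 with a filter of 5 CPM. Of the 12 cell type lists, 5 passed with the preset correlation and none with an estimated one. Eosinophil genes were higher in Ifnar1 -/- AML (10 of 10, median 3.90, camera adjusted p = 0.00871, adjusted p = 0.843 with an estimated correlation). Their values came from Ifnar1 -/- library 2. Without it the log2 fold change of Prg2 was -1.80, against 4.74 with it, and that of Alox15 -1.21 against 3.96. Monocyte and macrophage genes were lower in 16 of 22 (median -0.88, adjusted p = 0.00304, adjusted p = 0.843 with an estimated correlation), although their most abundant members Ly6c2 and Itgam had log2 fold changes of 4.30 and 2.85, which turned to -0.74 and -1.01 without that library.

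Erythroid genes were lower in 18 of 20 (median -1.31, adjusted p = 0.0162, adjusted p = 0.843 with an estimated correlation). Hbb-bs and Hba-a1 had 49495 and 35588 CPM in Ifnar1 +/- library 6 and at most 5202 and 3406 CPM in the others. Without that library their log2 fold changes were -0.14 and -0.13, against -2.47 and -2.57 with it. B cell genes were lower in 15 of 18 (median -0.57, adjusted p = 0.00639, adjusted p = 0.843 with an estimated correlation), with the highest values in 3 of 6 Ifnar1 +/- and 2 of 5 Ifnar1 -/- libraries. Cd79a had 1442 ± 1572 against 939 ± 1303 CPM and Ighm 1390 ± 1576 against 1045 ± 1411 CPM. Of the 22 T and NK cell genes only 8 could be tested, and Cd3e, Cd3g, Cd8a and Ncr1 were among those too low. Of the 8, 5 were lower (median -1.47, camera adjusted p = 0.0322, adjusted p = 0.474 with an estimated correlation). The granzyme gene Gzmb had 2115 ± 2733 against 341 ± 544 CPM and Lck 136 ± 167 against 75.1 ± 110 CPM. Lck was highest, at 452 CPM, in Ifnar1 +/- library 3, where B-lineage genes were abundant. These values therefore do not show a lower T or NK cell content.

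Lists of other cell types and programmes did not pass. Neutrophil genes had a median log2 fold change of 0.60 while camera pointed down (adjusted p = 0.396) and the score difference was -0.83 (exact permutation p = 0.652), with Ngp at 943 ± 933 and 5226 ± 10543 CPM. Stem and multipotent progenitor genes had an adjusted p of 0.851 in camera, which pointed down with a median of 0.12, and Adgrg1 had 611 ± 274 against 674 ± 403 CPM and Ly6a 718 ± 866 against 443 ± 592 CPM. Megakaryocyte and platelet genes had 11 of 14 higher (adjusted p = 0.211), with Itga2b at 540 ± 971 against 379 ± 474 CPM and Pf4 at 154 ± 219 against 172 ± 229 CPM. The camera adjusted p was 0.786 for granulocyte and monocyte progenitors, 0.234 for dendritic cells, 0.234 for mast cells and basophils and 0.234 for endothelial and stromal cells. It was 0.786 for the Hox programme, 0.234 for oxidative phosphorylation, 0.321 for NF-kB inflammation, 0.786 for p53 and apoptosis and 0.786 for immediate early genes. For granulocyte and monocyte progenitors (median 0.12), class II presentation (0.11), interferon receptors (0.04), p53 and apoptosis (0.05) and endothelial cells (0.08) camera also pointed down against the sign of the median. The mean had the other sign than the median for the Hox programme (median 0.02, mean -0.01) and, among those lists, for class II presentation (mean -0.01), interferon receptors (mean -0.07), p53 and apoptosis (mean -0.05) and endothelial cells (mean -0.00416).

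Genes near Ifnar1 were tested because a targeted allele can carry flanking DNA of another strain. Of 24 tested members of the fixed list 12 were lower (median -0.04, camera adjusted p = 0.637). Mis18a, a centromere assembly factor gene, had 58.5 ± 4.14 CPM (SD, n = 6) in Ifnar1 +/- and 44.4 ± 5.75 CPM (SD, n = 5) in Ifnar1 -/- AML and did not pass. Tiam1 had 10.2 ± 3.15 and 15.5 ± 5.91 CPM. Within 10 Mb on either side lay 80 tested genes, of which 0 were called in edgeR and 2 had an unadjusted p under 0.05, so the planned Fisher test of called genes had nothing to count. As a set, chosen after that was seen, these genes had a camera p of 0.0951.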

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

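The tests of the B-lineage pattern, of the granulocytic library and of the B cell list score as a covariate were chosen after the values had been seen, and the others before. How the heavy-chain V genes, the neutrophil genes and the genes of the cooperating mutations were read was also settled after their values had been seen. Among 180 groups of values examined for a library far from the rest of its genotype, 9 stood out, which is about the 1 in 20 that chance gives.

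Ifnar1 -/- library 2 had the lowest normalization factor of its group (0.682) and the lowest Irgm1 (3.99 log2 CPM). Ifnar1 -/- library 5 had the highest Rtp4 of its group (1.91 log2 CPM). Ifnar1 +/- library 6 had the highest Fyttd1 (6.01 log2 CPM) and the lowest mt-Nd3 (6.05), mt-Nd6 (5.46) and Tiam1 (2.15) of its group. Ifnar1 +/- library 2 had the highest class II presentation score of its group (0.77), and Ifnar1 +/- library 1 had the highest B2m of that group (12.03 log2 CPM).

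Lower interferon-stimulated genes in Ifnar1 -/- AML were weighed first. Library depth is argued against, since the score difference was -0.99 after all libraries were thinned to one total, against -0.998 before. No single library carried it, since the smallest difference with one library left out was -0.88. The B-lineage content of the AMLs is argued against as the whole cause. With the B cell list score as a covariate the difference was -0.90 (permutation p = 0.0238). This p is not exact, since genotype was permuted while each library kept its B cell score. What stays open as a hypothesis is that loss of the receptor may lower these genes, which the design confounds with anything else that differs between the genotypes.

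B-lineage transcripts in 5 AMLs were weighed next. Admixed mature B cells are argued against as the whole source, since Igkc reached at most 0.169 of the level of Cd79a in these libraries and Fcer2a was near 0. A smaller share of later B cells stays open, since Ms4a1 had 65.4 and 125 CPM in Ifnar1 +/- libraries 4 and 5 and 152 CPM in Ifnar1 -/- library 5, and Ighd had 79.4 CPM in Ifnar1 +/- library 5. Progenitors of the B lineage that are not leukaemic remain possible. In these 5 libraries no heavy-chain V gene took more than 30.4% of heavy-chain V counts (95% Wilson interval 26.8% to 34.4%), which a mixed population gives. In the libraries low in B-lineage transcripts the highest share ran from 13.1% to 32.7%, so a share of this size is not specific to the 5 libraries. In Ifnar1 -/- library 5 Igkv8-21 took 55.1% of light-chain V counts, which speaks against a mixed population there, but Igkv12-46 took 67.4% in Ifnar1 +/- library 6, where B-lineage transcripts were low, so such a share is not specific. AMLs that themselves express a B-lineage programme could give this too if they arose before heavy-chain rearrangement. None of these values separates the 2 explanations, and no biological explanation was tested, since the labels give no lineage.

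Granulocyte transcripts in Ifnar1 -/- library 2 were weighed last. Admixed neutrophils stay open. Of 20 tested neutrophil genes 13 were highest there, among them Retnlg with 8361 CPM and S100a9 with 3536 CPM, and 7 were not, among them Camp with 98.0 CPM and Ltf with 303 CPM. Cells without the cooperating mutations stay open too. All 3 of Flt3, Hoxa9 and Hoxd13 lay within the range of the other AMLs, but these ranges were wide (2.33 to 94.97 CPM for Hoxa9). Counts of Flt3 do not show its duplication, and counts of Hoxd13 do not show the fusion. An AML with eosinophilic and granulocytic maturation, or one whose genotype label is wrong, may remain, and neither was tested. This library also had 3 counts of Xist and 817 of Ddx3y, so sex and lineage cannot be separated in it.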

How the results depend on the processing

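The B cell list score as a covariate, the fit without a pair of libraries (Ifnar1 +/- library 6 and Ifnar1 -/- library 2) and the camera test of windows around Ifnar1 were chosen after seeing the data. The count of called genes was 0 in every edgeR and limma voom alternative, each library left out included, and 3 in DESeq2 (454 genes at an unadjusted p under 0.05). The interferon-stimulated gene list stayed lower, with its median between -0.75 and -0.31, and lost its call with an estimated correlation (adjusted p = 0.0762) and in fry (0.235 directional, 0.689 mixed; median -0.50 in each). Its score difference ran from -1.23 to -0.61 and kept a permutation p under 0.05 but for the replicate block. There 5 pairs cannot give a p under 0.0625. With the B cell score or the surrogate variable that p was not exact, since genotype alone was permuted. Lists called were 7 with the filter of 5 CPM (fewer genes tested), 0 with an estimated correlation and 0 in fry, and 5 to 11 with one library left out, the lowest being 5 without Ifnar1 +/- library 1 and 6 without Ifnar1 +/- library 4. The replicate numbers did not pair the libraries: deviations correlated at 0.52, 0.24, 0.62, -0.59 and 0.62 for numbers 1 to 5. Among Ifnar1 -/- libraries only library 2 correlated best with the Ifnar1 +/- library of its own number. With the replicate block 0 genes and 9 lists were called, and the score difference was -1.07 (exact permutation p = 0.125 over the pairs).

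The difference in spread stayed positive and without a call, from 0.00147 to 0.105 with one library left out and 0.0249 with the filter of 5 CPM. Genes near Ifnar1 had a median of 0.029 with the filter of 5 CPM and between -0.15 and 0.028 with one library left out. Ifnar1 had a log2 fold change of -0.25 in limma voom and between -0.20 and 0.34 with one library left out. Among named genes, none of which passed in edgeR, DESeq2 called Prf1 (-3.77), Nrp2 (-4.17) and Fyttd1 (-0.51). Signs turned with the block for Ly6a (0.73), Retnlg (-0.39), Hbb-bs (0.11), Hba-a1 (0.11) and Itga2b (0.75), with a surrogate variable for Ighm (0.12), and with the B cell score for Ighm (0.61) and Cd79a (0.60). Without the pair of libraries they turned for Ngp (-0.45), Retnlg (-2.45), Ly6c2 (-0.69), Itgam (-1.06), Prg2 (-2.08) and Alox15 (-1.48). In limma voom they turned for Ly6a (2.73), Ngp (-2.58), Retnlg (-1.57), Ly6c2 (-1.52), Itgam (-0.51), Hbb-bs (0.41), Hba-a1 (0.43), Itga2b (2.05), Gzmb (0.68), Prg2 (-1.57) and Alox15 (-0.27). With one library left out the ranges were -1.76 to 0.017 (Ly6a), -1.63 to 1.34 (Itga2b), -1.02 to 1.32 (Pf4), -2.20 to 0.042 (Lck), -1.25 to 0.16 (Ighm), -0.15 to 0.41 (Adgrg1), -0.85 to 2.90 (Ngp), -2.26 to 4.35 (Retnlg), -0.74 to 5.04 (Ly6c2), -1.01 to 3.90 (Itgam), -1.80 to 5.61 (Prg2) and -1.21 to 5.19 (Alox15). Of genes named in the report, further fold changes kept their sign but moved by over 1.5 times, besides those the report gives without a library. Their ranges were 0.83 to 1.63 (Paox), 0.18 to 0.44 (Irf1), -2.08 to -1.06 (Egr1), -1.52 to -0.25 (Cd79a) and -4.39 to -1.92 (Gzmb). The others were -0.86 to -0.29 (Kif11), -0.87 to -0.21 (Ccnb1), -0.53 to -0.28 (Eif4e), 0.39 to 0.75 (Tiam1) and -0.37 to -0.14 (mt-Nd6). Apart from these and fewer samples or genes, the cause was not tested. A sex covariate was not fitted, since Xist was nearly absent from 1 library alone. Depth limits genes near 1 CPM, such as Oas2.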

Other observations

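The test of carry-over and the simulation of the interaction below were chosen after the values had been seen. Interferon-stimulated genes did not follow one pattern among the Ifnar1 +/- AMLs. Isg15, which encodes a ubiquitin-like modifier, had 46.7, 58.5, 5.55, 3.96, 4.30 and 68.7 CPM in libraries 1 to 6. Rsad2, the viperin gene, had 5.04, 24.2, 0.828, 3.56, 1.40 and 28.6 CPM. Ifi27l2a was high where these were low, with 0.242, 5.71, 29.6, 47.3, 49.4 and 0.649 CPM in the same order. The B cell list score of these libraries was -3.11, -0.99, 3.70, 4.65, 4.87 and -4.20. In Ifnar1 -/- AML, Isg15 ran from 1.68 to 12.6 CPM. Genes of this paragraph were chosen after their values were seen.

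Some transcripts were set beside markers of other lineages. Gzmb, a cytotoxic granule gene, had 6252 CPM in Ifnar1 +/- library 1, 4866 CPM in library 6 and 1302 CPM in Ifnar1 -/- library 4, while the T-cell receptor complex gene Cd3e had at most 0.357 CPM in any library. In the same order the mast cell and basophil list score was 2.91, 0.84 and 1.55. It was 1.89 in Ifnar1 +/- library 2, which had 1123 CPM of Gzmb, and at most 0.016 in the remaining libraries. Trac, the T-cell receptor alpha constant gene, had 289 CPM in Ifnar1 +/- library 2, 164 CPM in Ifnar1 -/- library 1 and 184 CPM in Ifnar1 -/- library 4. Ifnar1 -/- library 5 had B-lineage transcripts together with 95.1 CPM of Itga2b and 16.6 CPM of Mecom, where Ifnar1 +/- libraries 3, 4 and 5 and Ifnar1 -/- library 3 had 8.59 to 57.9 CPM of Itga2b and at most 3.85 CPM of Mecom. In the same library a single light-chain gene, Igkv8-21, took 55.1% of light-chain V counts (95% Wilson interval 53.9% to 56.3%). Ifnar1 -/- library 3, with 1602 counts of Xist, also had 47 counts of the Y-linked gene Eif2s3y, against 1551 in Ifnar1 -/- library 2. Carry-over from library 2 is argued against, since Eif2s3y at 2.10% of its CPM there predicts 1003 CPM of Prg2 in library 3, and the observed level was 12.01% of that. The source of these counts stays open.

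Splits of the 11 libraries into 6 and 5 were drawn 100 times, the real one included, and these counts were planned before they were seen. All 100 splits called at least the 0 genes of the real one, which any split must, so this count says nothing about chance. The highest other split called 3033. A split that calls so many points to a structure of the samples. In that split the B cell list score differed by -6.25, while another split with a difference of 6.27 called 0 genes and one with 4.77 called 673. A difference in mean score does not show how mixed each side was. These splits therefore do not test whether B-lineage content gave the called genes. For the 11 lists called with the preset correlation, 47 splits called as many or more (highest other 18), so chance is not excluded for that number. For the interferon-stimulated gene list, 1 of the 100 splits, the real one, gave so small a camera p (4.1e-17). The smallest camera p of the other splits was 1.7e-14. Since the real split is counted, the share of splits cannot be smaller than 1 of 100. It was not adjusted for the 28 lists, so it does not exclude chance for that camera p. Other splits also gave very small p with the preset correlation. Nor is chance excluded for the score of the list over the 28 lists (exact permutation p = 0.0152, adjusted p = 0.424).

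One hypothesis, written before its result was seen, was that the genotype may have an effect that varies with the B-lineage score of the AML. In edgeR's interaction test 0 genes passed, the smallest adjusted p being 0.999, and 613 had an unadjusted p under 0.05, 2 of them among the 49 interferon-stimulated genes. As first written, 0 genes would have counted against the hypothesis. That reading was changed after the result was seen, and the result is taken not to exclude such an effect, since the test had little power. When a genotype effect that grew with the score was simulated with the dispersions of these libraries, 0 of the 2-fold, 4-fold or 8-fold effects were called, against 7.46%, 61.2% and 95.5% at a dispersion of 0.05.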
